A study of Homo sapiens with 12 samples.

How the data were processed

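RNA from Z138 cells was measured by short-read sequencing in 12 samples, 3 each of AU-15330 (0.5 µM) and DMSO at 8 h and at 24 h. Per the labels, reads of 50 bp came from a NextSeq2000 and libraries were made with either a poly(A) or a ribosomal depletion kit of the TruSeq family; which kit was used for which sample is not given in the sources used here. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.40, kallisto 0.46.1, R 4.3.2, DESeq2 1.24.0 and the genome build GRCh38.p13, without parameters.

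The deposited table holds log2 values for 20318 gene entries with Ensembl identifiers. Their properties were read from the values themselves. The lowest value was 10.36053 in all 11 libraries and the highest was 20.152, which fits a variance-stabilising transform of normalised counts and not log CPM. Inverting that transform gave normalised counts. After dividing by the worth of 1 count, between 53.5% and 56.0% of values up to 20 counts lay within 0.02 of a whole number, and the rest were fractions, as estimated counts from kallisto can be. Because whole reads were not recovered for nearly all genes, no count model was the main test. Estimated total counts were 50765418 to 67572111 per library. On the deposited scale a doubling is a difference of 0.163 at 100 normalised counts, 0.461 at 1000 and 0.852 at 10000, so differences on that scale understate fold changes, most of all for low genes. For this reason folds are reported on log2(normalised count + 60), where 60 is close to the 59.4 normalised counts that equal 1 CPM, and adjusted p-values come from the deposited scale. Folds of low genes are still understated on that scale.

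The table has 12 columns of values. A pair of columns carries the same name and identical values, so 1 column was not used, and 1 sample, DMSO replicate 3 at 8 h, had no column of its own. The planned design assumed 12 libraries, log CPM and 8 residual degrees of freedom. The fit used 11 libraries, the transformed values and 7 residual degrees of freedom. Groups were taken from sample titles.

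Symbols were deposited with the table. In it 1600 entries had no symbol, and 832 symbols had more than 1 entry (2318 entries, of which 1496 were absent from the primary assembly). Identifiers were matched to GENCODE release 29 on GRCh38 for coordinates, and 18573 entries (91.41%) matched. For a symbol with several entries, the entry on the primary assembly was used, and its value is uncertain because reads can be shared with the copies. Strand use in counting is not given in the sources used here, so overlapping genes and antisense partners are uncertain as well.

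Entries with at least 1 CPM in at least 3 libraries were tested, 12721 in all (62.6%). A linear model with 1 mean per group was fitted in limma 3.58.1 under R 4.3.3 with a mean-dependent prior for the variance, and contrasts were AU-15330 against DMSO at 8 h, the same at 24 h, the difference between these effects, and DMSO at 24 h against 8 h. All groups shared the estimate of the spread. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Gene lists were fixed before the data were examined, as were the main model, the naming rule and most alternatives. Of 28 lists, the 25 with at least 5 tested members went into limma's camera with a preset correlation of 0.01, and camera with an estimated correlation and fry were alternatives. Markers of T cells, myeloid cells, erythroid cells and megakaryocytes had fewer tested members and are given as values. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.

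Genes named in the text follow a rule. For each treatment comparison it takes the 8 largest rises and 8 largest falls on the deposited scale among genes past the threshold with a mean of at least 5 CPM in the higher group, non-overlapping groups and a proper gene symbol. It adds 10 genes that are always named and, for each list, the 4 members with the smallest p. For the difference between the times it takes the 5 largest in each direction. List members named in addition were chosen after their values were seen.

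The procedure was tested on simulated data drawn from the real means and spreads. For the 8 h comparison (12588 genes) it recovered 30%, 72%, 80% and 98% of genes changed by 1.25, 1.5, 2 and 4-fold, and 6.21% of its calls were false. For the 24 h comparison (12617 genes) it recovered 44%, 72%, 82% and 96%, and 2.99% of calls were false. Few genes were changed, with 50 scored at each size, and 161 genes were called at 8 h and 167 at 24 h. In the data 44.2% and 50.9% of genes were called. The adjusted threshold is stricter when few genes change, so these rates do not carry over to the data.

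Alternatives were quantile normalisation, centring of library medians, log2(CPM + 1) and log2(CPM + 5), no filter and a filter at 5 CPM, a minimum absolute difference of 1 on the deposited scale, a fit within each comparison's own groups, variance priors that were robust or without a trend, a replicate block and leaving out each of the 11 libraries. After the data were seen, voom on the recovered counts, the summing of entries with the same symbol, and a test on log2(count + 60) were added. No reads were analysed.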

Results

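RNA was sequenced from Z138, a human mantle cell lymphoma cell line, after 8 h or 24 h in 0.5 µM AU-15330 or in the DMSO vehicle. AU-15330 is a proteolysis-targeting chimera that degrades SMARCA2 and SMARCA4, the ATPases of the BAF chromatin remodelling complexes, and PBRM1, a subunit of the PBAF form. The labels list 12 samples in 4 groups of 3. At 8 h, 2 identical columns carried the library name of DMSO replicate 2, which the description of DMSO replicate 3 also gives as its column. No column carried a name of replicate 3 alone. The duplicate was counted as 1 sample, called replicate 2 here, and 11 libraries were analysed. Which of these replicates the values belong to is not settled. DMSO at 8 h therefore had n = 2, and AU-15330 at 8 h, AU-15330 at 24 h and DMSO at 24 h each had n = 3. The estimated total counts lay between 50765418 and 67572111 per library. Fold changes are given as log2 of the normalised count plus 60, with the standard error (SE), and adjusted p-values come from limma with Benjamini-Hochberg adjustment over the 12721 genes tested. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. They also give each time its own batch, and every AU-15330 library was compared with DMSO libraries of the same time and batch.

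Libraries separated by treatment first and by time second. The first principal component held 62.2% of the variance and placed the 6 AU-15330 libraries between -12.03 and -9.731 and the 5 DMSO libraries between 11.23 and 14.07. The second component held 20.2% and separated 8 h from 24 h within each treatment. Pearson's r across genes was at least 0.9965 between libraries of 1 group, 0.981 to 0.982 between AU-15330 and DMSO at 8 h, and 0.975 to 0.978 between them at 24 h. Genes are not independent replicates, and these correlations describe the libraries only.

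The genes that encode the proteins degraded by AU-15330 were measured in every library as a background to the other changes. SMARCA4 (GRCh38 chromosome 19, 10960825 to 11079426) averaged 37930 ± 218 normalised counts in DMSO at 8 h (SD, n = 2) and 33960 ± 2000 in AU-15330 (SD, n = 3), a log2 change of -0.16 ± 0.0532 (limma adjusted p = 0.0294), and its change at 24 h was -0.28 ± 0.0476. SMARCA2 (chromosome 9, 1980290 to 2193624) fell by 0.48 at 8 h and by 0.87 at 24 h on the log2 scale, with limma adjusted p-values of 0.000261 and 1.1e-06. PBRM1 (chromosome 3, 52545352 to 52685917) had a log2 change of 0.00 ± 0.0566 at 8 h, which did not pass the test, and fell by 0.16 at 24 h (limma adjusted p = 0.0189). The values are RNA levels, and no protein was measured.

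Of the genes characteristic of mantle cell lymphoma and of B cells that were fixed in advance, PAX5, BCL2 and CXCR4 were lower under AU-15330 at both times. PAX5, a master regulator of B cell identity, went from 7170 ± 1050 normalised counts in DMSO to 2532 ± 313 at 8 h, a log2 change of -1.48 ± 0.111, and the change was -1.03 ± 0.099 at 24 h. BCL2, an inhibitor of apoptosis, changed by -1.44 ± 0.0892 and -1.13 ± 0.0797, and CXCR4, a homing receptor, by -0.43 ± 0.0334 and -0.91 ± 0.0299. SOX11, a transcription factor expressed in most mantle cell lymphomas, averaged 5057 ± 367 normalised counts in DMSO and 11310 ± 373 in AU-15330 at 24 h (SD, n = 3 each), a log2 change of 1.15 ± 0.078 (limma adjusted p = 2.1e-07), while its change of 0.19 ± 0.0872 at 8 h did not pass the test. MYC rose by 0.35 ± 0.0264 at 8 h and was lower by -0.19 ± 0.0236 at 24 h. CD70, a TNF family ligand, had a change of 0.03 ± 0.0658 at 8 h and rose by 0.30 ± 0.0589 at 24 h. CCND1, the cyclin D1 gene activated in mantle cell lymphoma, had changes of -0.04 ± 0.0313 and -0.01 ± 0.028, neither of which passed the test. After quantile normalisation the CCND1 change at 24 h was 0.11 on the deposited scale (limma adjusted p = 0.00226, against 0.00226 to 0.975 over its alternatives).

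**Figure D1:**
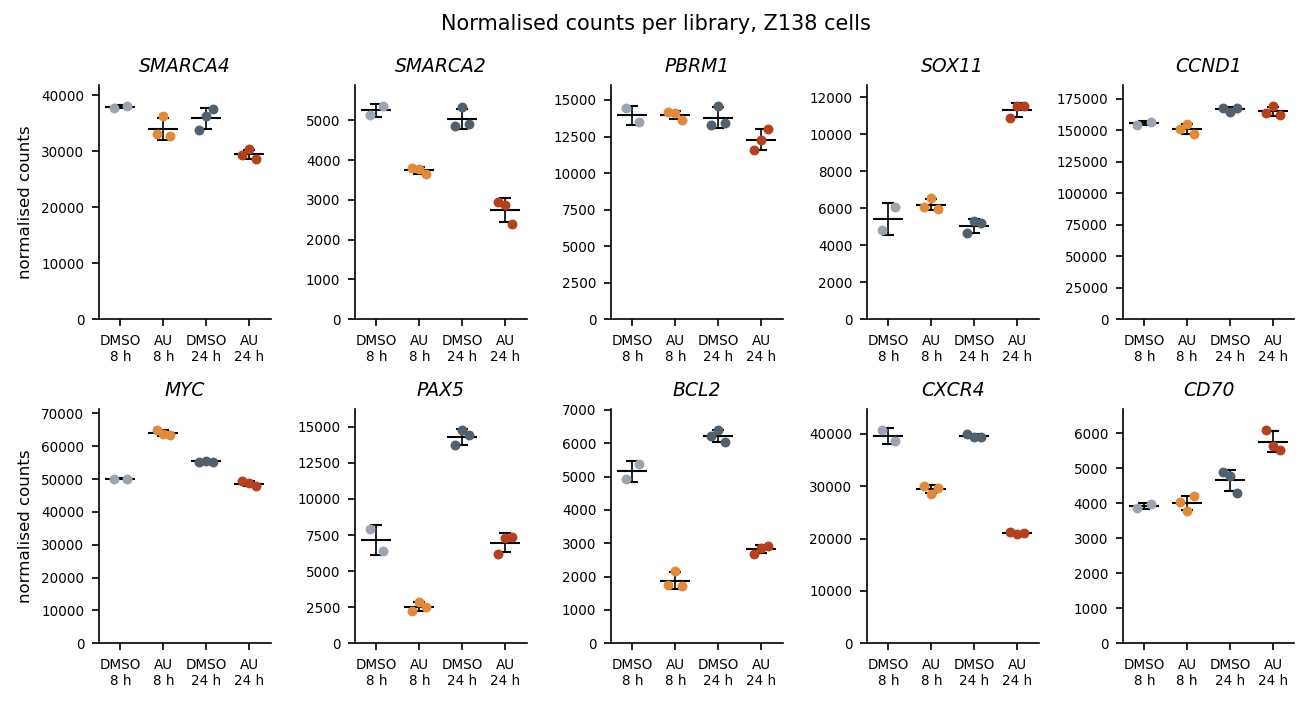
Normalised counts (vertical axes, linear from 0) of the 10 genes named in every comparison, with 1 point per library and a bar for the mean ± SD of each group (DMSO at 8 h, n = 2; all other groups, n = 3). SOX11 reached a mean of 11310 in AU-15330 at 24 h against 5057 in DMSO, and PAX5 fell to a mean of 2532 in AU-15330 at 8 h against 7170 in DMSO.

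At 8 h, surface receptor and signalling genes of B cells were lower under AU-15330, and cholesterol synthesis genes, CRYM, SLC7A5 and SOCS3 were higher. SASH3, a lymphocyte signalling adaptor (chromosome X, 129779979 to 129795201), fell from 3111 ± 153 to 176 ± 17.6 normalised counts (SD, n = 2 and n = 3), a log2 change of -3.75 ± 0.0846 (limma adjusted p = 6.66e-10). CRYM, which encodes a thyroid hormone binding protein (chromosome 16, 21238874 to 21303083), rose from 105 ± 1.91 to 1680 ± 208, a log2 change of 3.39 ± 0.114 (limma adjusted p = 3.37e-08). In all, 5624 of the 12721 genes passed the test, of which 2907 were higher and 2717 lower. The share lower was 48.3% on the deposited scale and 44.7% after quantile normalisation, and on log2(CPM + 5) 2770 were higher and 2773 lower. Among those that changed at least 2-fold, 122 were higher and 481 lower.

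The largest rises at 8 h on the deposited scale were in SLC7A5, SPIB, HBEGF, EIF4A3, CRYM, GADD45B, RNF213 and SOCS3. By fold the order differs, and EGR1, given below, rose further than EIF4A3. SLC7A5, the light chain of a large neutral amino acid transporter (chromosome 16, 87830023 to 87869488), rose by 1.66 ± 0.0515 from an already high 49190 ± 4060 normalised counts. SPIB, an ETS family transcription factor, rose by 1.82 ± 0.0757, and SOCS3, a feedback inhibitor of cytokine signalling, by 2.38 ± 0.102. EIF4A3, an RNA helicase of the exon junction complex, rose by 1.29 ± 0.041, and GADD45B, a stress-inducible gene, by 1.52 ± 0.0812. The largest falls on the deposited scale were in ZMIZ1, IGLC2, SASH3, CCR7, TNFRSF1B, CHD4, CD38 and CD48. By fold the order differs, and LCK and GPR183, given below, fell further than CHD4. CCR7, a chemokine receptor of lymph node homing, changed by -3.24 ± 0.0906, TNFRSF1B, a TNF receptor, by -3.41 ± 0.125, and ZMIZ1, a transcriptional coregulator, by -2.44 ± 0.08. CHD4, the ATPase of the NuRD chromatin remodelling complex, went from 46510 ± 1130 to 15720 ± 1440 normalised counts (-1.57 ± 0.0641), and CD38, an ectoenzyme, changed by -2.16 ± 0.127. IGLC2, an immunoglobulin light chain constant gene, changed by -2.10 ± 0.0995, but it shares reads with near-identical neighbouring genes and its value is uncertain. These 16 genes were chosen among those whose library values did not overlap between groups, which chance gives for 20% of unchanged genes with 3 libraries against 2.

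Of 31 tested members of the B cell receptor signalling list, 3 rose, 23 fell and 5 did not pass the test at 8 h (4 and 23 adjusted over the list alone). CD79B, a signalling chain of the receptor, changed by -1.63 ± 0.0743, CD72 by -2.01 ± 0.116, MS4A1, which encodes CD20, by -0.87 ± 0.0444 and CD81 by -0.94 ± 0.0496. The list's median was -0.68 (camera adjusted p = 3.45e-08, and adjusted p = 0.0494 with an estimated correlation). CD72, CD22, FCGR2B, PTPN6 and INPP5D, which restrain receptor signalling, were among the members that fell, and PTPN6 changed by -0.44 and INPP5D by -1.14. INPP5D has 2 entries in the table. Of 4 tested T cell markers, LCK (-2.53 ± 0.101), CD4 (-1.26 ± 0.128) and CD3G (-1.17 ± 0.126) were lower with this group and CD28 (0.97 ± 0.229) was higher, with 1 higher and 3 lower adjusted over the list alone.

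The plasma cell differentiation list fell at 8 h, with 2 of 16 members higher, 10 lower and 4 not past the test (2 and 10 adjusted over the list alone). MZB1, which promotes antibody secretion, changed by -1.89 ± 0.0659 and XBP1, a secretory regulator, by -0.74 ± 0.0573, whereas PRDM1, which drives plasma cell fate, rose (limma adjusted p = 8.15e-06). For the list, camera gave an adjusted p of 0.00243, and adjusted p = 0.0629 with an estimated correlation. Of 18 unfolded protein response genes, 2 rose, 11 fell and 5 did not pass the test (2 and 11 adjusted over the list alone), with a median of -0.25. HSPA5, the main chaperone of the endoplasmic reticulum, changed by -0.63 ± 0.0313 and EDEM1 by -0.60 ± 0.0473. With camera the adjusted p was 0.00243, and adjusted p = 0.0966 with an estimated correlation.

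Homing and adhesion genes were lower at 8 h. Of 21 members, 2 rose, 13 fell and 6 did not pass the test (2 and 14 adjusted over the list alone), with a median of -0.60. GPR183, a B cell positioning receptor, changed by -2.40 ± 0.0987, ICAM1 by -1.16 ± 0.0709 and GNAI2 by -0.58 ± 0.0427, while S1PR1, an egress receptor, rose by 0.70. Camera gave an adjusted p of 7.3e-05, and adjusted p = 0.0494 with an estimated correlation. Interferon response genes were lower as well, with 4 of 22 higher, 14 lower and 4 not past the test (5 and 14 adjusted over the list alone). IRF1 changed by -1.67 ± 0.0642, MX1 by -2.37 ± 0.122 and IFIT5 by -1.39 ± 0.0945, and OAS1 rose by 1.62 ± 0.113. Their median was -0.60 (camera adjusted p = 0.00226, and adjusted p = 0.0494 with an estimated correlation).

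Of 24 cholesterol biosynthesis genes, 21 rose, 1 fell and 2 did not pass the test at 8 h, and the counts were 21 and 1 adjusted over the list alone. HMGCS1 rose by 1.21 ± 0.0617, SQLE by 1.09 ± 0.0543 and CYP51A1 by 1.02 ± 0.0512, while TM7SF2, a sterol reductase, changed by -0.69. The median was 0.53 (camera adjusted p = 1.94e-07, and adjusted p = 0.0494 with an estimated correlation). MYC targets and ribosome biogenesis genes rose by less, with 17 of 40 higher, 2 lower and 21 not past the test (17 and 2 adjusted over the list alone) and a median of 0.11. GART, a purine synthesis enzyme, rose by 0.40 ± 0.038, WDR12 by 0.39 ± 0.0408 and PES1, a ribosome biogenesis factor, by 0.29 ± 0.0365. For this list the camera adjusted p was 0.00243, and adjusted p = 0.0494 with an estimated correlation.

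Of 25 p53 targets, 3 rose, 15 fell and 7 did not pass the test at 8 h (3 and 15 adjusted over the list alone). CDKN1A, an inhibitor of cyclin-dependent kinases, changed by -1.09 ± 0.0701 and TP53INP1 by -1.76 ± 0.124, and BTG2, an antiproliferative gene, rose by 1.20 ± 0.0629. The p53 list had a camera adjusted p of 0.00172, and adjusted p = 0.141 with an estimated correlation. Of 35 mitosis genes, 2 rose, 13 fell and 20 did not pass the test (2 and 16 adjusted over the list alone), with HMMR at -0.53 ± 0.0435 and KIF2C at -0.38 ± 0.0403. The list's median was -0.13 (camera adjusted p = 0.00423, and adjusted p = 0.229 with an estimated correlation). The 10 genes described as SOX11 targets in mantle cell lymphoma were 1 higher, 6 lower and 3 not past the test (1 and 6 adjusted over the list alone), and PDGFA, a growth factor, changed by -1.59 ± 0.101 and DBN1 by -0.84 ± 0.0505. Their camera adjusted p was 0.00423, and the adjusted p = 0.0563 with an estimated correlation.

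Other subunits of the remodelling complexes were higher at 8 h. Of 26 BAF and PBAF genes, 11 rose, 2 fell and 13 did not pass the test (11 and 2 adjusted over the list alone). BICRAL rose by 0.88 ± 0.0571, DPF1 by 1.34 ± 0.159, ARID1B by 0.48 ± 0.0507 and ARID1A by 0.44. The median was 0.09 (camera adjusted p = 0.029, and adjusted p = 0.0966 with an estimated correlation), and the camera adjusted p was 0.119 after quantile normalisation, against a range of 0.0291 to 0.119 over 3 other scalings. B cell transcription factors had 5 of 28 members higher, 12 lower and 11 not past the test (5 and 13 adjusted over the list alone), among them SPI1, which encodes PU.1, at -2.28 ± 0.111 and IRF8 at -1.81 ± 0.167. That list missed the threshold with a camera adjusted p of 0.0592, and passed after quantile normalisation with 0.0257, in a range of 0.0257 to 0.0583 over the same scalings, and adjusted p = 0.34 with an estimated correlation.

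At 24 h, surface and signalling genes of B cells were again lower, several of them further below DMSO, and CRYM, BTG2, TYMP and SOX11 were higher. SASH3 went from 4461 ± 238 to 76.0 ± 2.66 normalised counts (SD, n = 3 each), a log2 change of -5.05 ± 0.0757 (limma adjusted p = 7.94e-12). CRYM went from 27.9 ± 3.79 to 2231 ± 228, a log2 change of 4.70 ± 0.102 (limma adjusted p = 5.31e-10). In all, 6476 of the 12721 genes passed the test, 3146 higher and 3330 lower. That balance turned with the scaling, with a share lower of 51.4% on the deposited scale, 46.3% with library medians centred, 43.0% after quantile normalisation, 42.5% on log2(CPM + 1) and 42.4% on log2(CPM + 5). Among those changed at least 2-fold, 209 were higher and 609 lower.

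The largest rises at 24 h on the deposited scale were in CRYM, BTG2, SLC7A5, SPIB, HBEGF, TYMP, ZNF703 and ADM. By fold the order differs, and HMOX1, given below, rose further than SLC7A5. BTG2 (chromosome 1, 203305491 to 203309602) rose by 2.11 ± 0.0563, TYMP, which encodes thymidine phosphorylase, by 2.54 ± 0.0929, and ZNF703, a zinc finger repressor, by 2.03 ± 0.115. ADM, a vasoactive peptide hormone, rose by 1.85 ± 0.0806, and HBEGF, a ligand of the EGF receptor, by 1.32 ± 0.0791. The largest falls on the deposited scale were in SASH3, CD38, ZMIZ1, IGLC2, CUX2, SH3TC1, CD81 and CD48. By fold the order differs, and GPR183 and LCK, given below, fell further than CD81. CD38 (chromosome 4, 15778275 to 15853230) changed by -3.02 ± 0.114, CUX2, a homeobox gene, by -3.09 ± 0.0471 and SH3TC1 by -3.25 ± 0.0978. CD81, a tetraspanin, went from 28730 ± 181 to 7014 ± 207 normalised counts, and CD48, an adhesion molecule, from 5077 ± 141 to 406 ± 22.0. Non-overlapping values, which these 16 genes were required to have, are given by chance for 10% of unchanged genes with 3 libraries against 3.

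Of the 31 B cell receptor signalling genes, 2 rose, 25 fell and 4 did not pass the test at 24 h (2 and 25 adjusted over the list alone). BTK, the kinase targeted in treatment of this lymphoma, changed by -2.50 ± 0.0632, MS4A1 by -1.75 ± 0.0397, PTPN6 by -2.62 ± 0.0821 and CD79B by -2.23. The median was -0.96 (camera adjusted p = 9.53e-11, and adjusted p = 0.078 with an estimated correlation). CD37 rose by 1.13 and BLNK, a linker of the receptor, by 0.26. The inhibitory members CD72 (-2.49), CD22 (-2.42), PTPN6, INPP5D (-1.57) and FCGR2B (-0.96) were lower here too. Of the T cell markers, LCK (-3.23 ± 0.0904), CD3G (-2.33 ± 0.112) and CD4 (-1.51 ± 0.114) were lower with the group as at 8 h. CD28 was higher (2.62 ± 0.205), with 1 higher and 3 lower adjusted over the list alone.

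Of 28 B cell transcription factors, 7 rose, 16 fell and 5 did not pass the test at 24 h (8 and 16 adjusted over the list alone). SPI1 changed by -2.91 ± 0.0997, POU2AF1, a B cell coactivator, by -1.45 ± 0.0544, TCF3 by -0.76 ± 0.0286 and IRF4 by -0.71 ± 0.0322, while SPIB rose by 1.41 ± 0.0677. Camera gave this list an adjusted p of 0.0102, and adjusted p = 0.235 with an estimated correlation. MHC class II genes were lower, with 2 of 14 higher, 9 lower and 3 not past the test (2 and 9 adjusted over the list alone). CIITA, the class II transactivator, changed by -1.19 ± 0.0849 and CD74, the invariant chain, by -0.67 ± 0.051, and RFX5, a class II promoter factor, rose by 0.55 ± 0.0395. For MHC class II the camera adjusted p was 0.00543, and adjusted p = 0.132 with an estimated correlation. Most HLA members have several entries on alternate haplotypes, and HLA-DPB1, at -0.99 ± 0.0753, is uncertain for that reason.

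Plasma cell, unfolded protein response, homing and interferon genes were lower at 24 h as well. In the plasma cell list 2 rose, 11 fell and 3 did not pass the test (2 and 11 adjusted over the list alone), with MZB1 at -1.30 ± 0.0589 and XBP1 at -0.83 ± 0.0513 (camera adjusted p = 0.000536, and adjusted p = 0.078 with an estimated correlation). In the unfolded protein response list 0 rose, 13 fell and 5 did not pass the test (0 and 13 adjusted over the list alone), with HSPA5 at -0.45 ± 0.028 and SEC61B, a translocon subunit, at -0.60 ± 0.0437. Its camera adjusted p was 0.000306, and the adjusted p = 0.078 with an estimated correlation. In the homing list 4 rose, 14 fell and 3 did not pass the test (4 and 14 adjusted over the list alone), with GPR183 at -4.22 ± 0.0883 and CCR7 at -2.46 ± 0.081, while S1PR1 (limma adjusted p = 1.01e-07) and SELPLG, a selectin ligand (1.34), rose. Its camera adjusted p was 0.00753, and the adjusted p = 0.162 with an estimated correlation. In the interferon list 5 rose, 15 fell and 2 did not pass the test (5 and 15 adjusted over the list alone), with IRF1 at -1.84 ± 0.0574 and IFIH1, an RNA sensor, at -0.82 ± 0.0506 (camera adjusted p = 0.00579, and adjusted p = 0.078 with an estimated correlation).

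Cholesterol biosynthesis was the list that rose at 24 h, with 17 of 24 members higher, 2 lower and 5 not past the test (17 and 2 adjusted over the list alone). DHCR7, which catalyses the last step of the pathway, rose by 1.11 ± 0.0723, HMGCS1 by 1.00 ± 0.0552 and SQLE by 0.86 ± 0.0486. The camera adjusted p was 1.31e-05, and the adjusted p = 0.078 with an estimated correlation. TM7SF2 (-1.09) was among the members that fell.

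**Figure D2:**
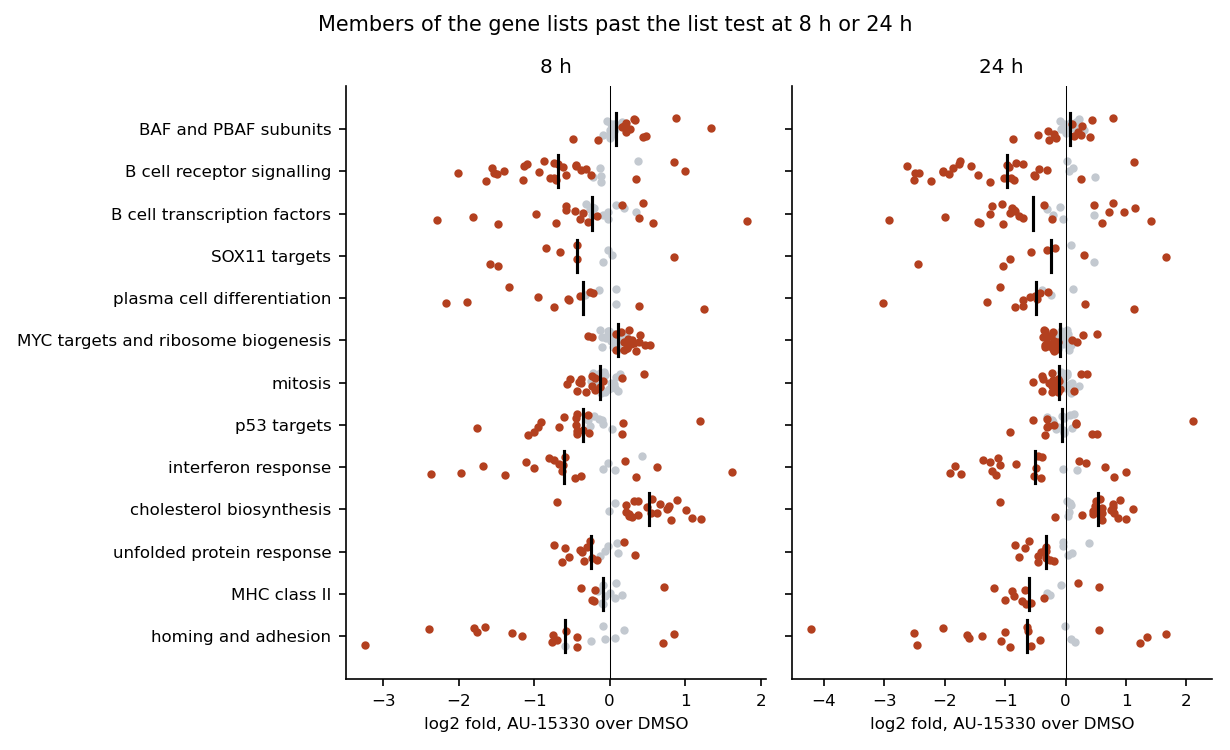
Log2 fold changes under AU-15330 (horizontal axes) of the members of the 13 gene lists past the list test at 8 h or at 24 h, with red points for genes past the limma test, grey points for other genes and a black tick at each list's median. The B cell receptor signalling medians lay at -0.68 and -0.96, and the cholesterol biosynthesis median lay at 0.53 at 8 h.

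Other lists did not pass the list test at the times given here. S phase and DNA replication genes went both ways, with 11 of 35 higher, 8 lower and 16 not past the test at 8 h (11 and 8 adjusted over the list alone, camera adjusted p = 0.939) and 9 higher, 14 lower and 12 not past the test at 24 h (9 and 14 adjusted over the list alone, camera adjusted p = 0.809). UHRF1, a maintenance methylation factor, changed by -0.66 ± 0.0432 at 8 h, TYMS by -0.40 ± 0.0292, and CCNE1, the cyclin E1 gene, rose by 0.59 ± 0.0727 at 24 h. The sign of this list's camera test turned with the scaling at each time, and at 24 h its median was 0.00218 and its mean -0.0143. At 24 h, MYC targets had 4 members higher, 18 lower and 18 not past the test (4 and 18 adjusted over the list alone, camera adjusted p = 0.0733), with TFRC, the transferrin receptor, at 0.52 ± 0.027 and ODC1, a polyamine synthesis enzyme, at -0.37 ± 0.0297. Mitosis genes were 3 higher, 18 lower and 14 not past the test at 24 h (3 and 18 adjusted over the list alone, camera adjusted p = 0.0622), p53 targets 5, 7 and 13 (5 and 7 adjusted over the list alone, camera adjusted p = 0.822) and SOX11 targets 2, 6 and 2 (3 and 6 adjusted over the list alone, camera adjusted p = 0.131). The mitosis counts at 24 h were 7 higher and 10 lower after quantile normalisation, and 6 and 10 on log2(CPM + 1). BAF and PBAF genes were 8 higher, 6 lower and 12 not past the test at 24 h (8 and 6 adjusted over the list alone, camera adjusted p = 0.535), and MHC class II genes were 1 higher, 4 lower and 9 not past the test at 8 h (1 and 4 adjusted over the list alone, camera adjusted p = 0.586).

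Most genes that passed the test at both times moved in the same direction. Of 4007 such genes, 1782 were higher at both times and 2035 lower at both, against 719 and 711 for independent lists of the same sizes. On the deposited scale, SASH3, CD38, ZMIZ1, IGLC2 and CD48 were among the largest falls at both times, and SLC7A5, SPIB, HBEGF and CRYM among the largest rises. Another 107 genes were higher at 8 h and lower at 24 h, among them MYC, EGR1 and IRF4, and 83 were lower at 8 h and higher at 24 h, among them SELPLG, against 761 and 672 for independent lists. Across all tested genes Pearson's r between the 8 h and 24 h fold changes was 0.751, and genes are not independent replicates. The 2 times had separate DMSO libraries.

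**Figure D3:**
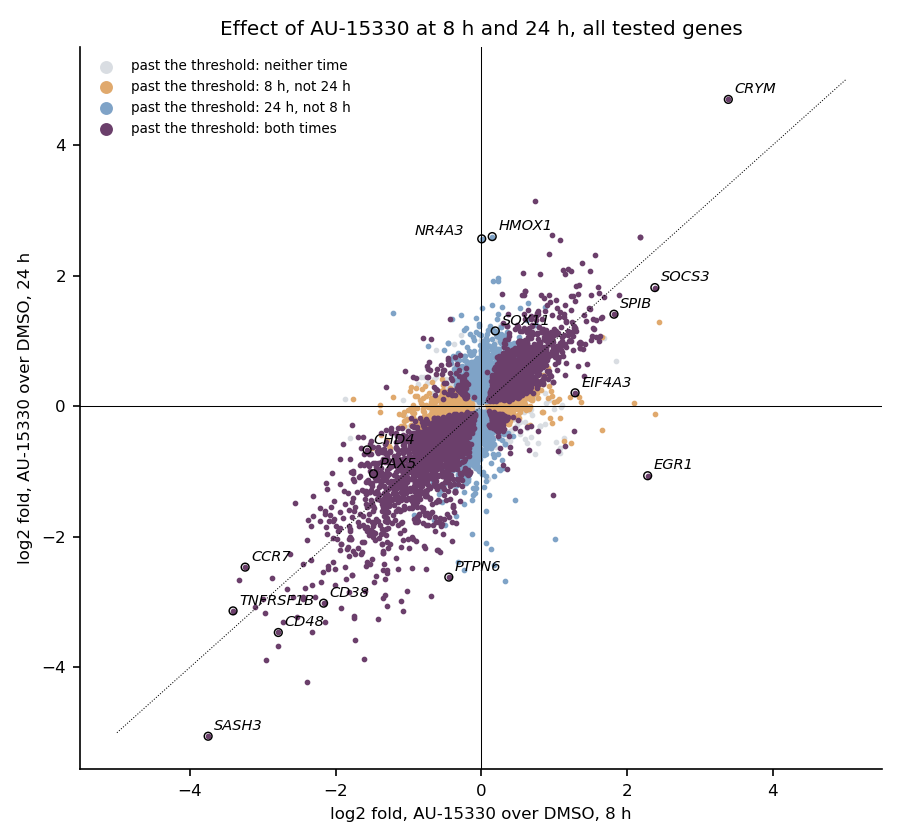
Log2 fold change under AU-15330 at 24 h (vertical axis) against that at 8 h (horizontal axis) for the 12721 genes tested, with a dotted line where both are equal. SASH3 lay at -3.75 and -5.05, and CRYM at 3.39 and 4.70.

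The effect of AU-15330 differed between the times for 2358 genes, HMOX1, NR4A3, EGR1 and PTPN6 among them, by a direct test of the 24 h change minus the 8 h change. HMOX1, the inducible heme oxygenase (chromosome 22, 35380361 to 35394214), had a change of 0.15 at 8 h and 2.60 at 24 h, a difference of 2.45 ± 0.167 (limma adjusted p = 6.23e-06). NR4A3, an orphan nuclear receptor, averaged 19.2 ± 3 normalised counts in DMSO at 8 h and 107 ± 34.1 at 24 h. Under AU-15330 it averaged 19.7 ± 4.44 and 928 ± 200, with a difference of 2.56 ± 0.259 (limma adjusted p = 0.000137). Both 8 h means lay below the 59.4 normalised counts that equal 1 CPM. EGR1, an immediate early transcription factor (chromosome 5, 138465490 to 138469315), was higher by 2.28 at 8 h and lower by -1.06 at 24 h, a difference of -3.35 ± 0.389 (limma adjusted p = 0.00108). Its DMSO mean was 288 ± 101 normalised counts at 8 h and 5788 ± 1750 at 24 h, against 1621 ± 341 and 2722 ± 717 under AU-15330. PTPN6, the phosphatase SHP-1, averaged 1242 ± 14.2 in DMSO at 8 h and 4674 ± 106 at 24 h, against 900 ± 89.0 and 714 ± 76.9 under AU-15330, a difference of -2.17 ± 0.123.

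Further genes with a positive difference were PLXNB2, a semaphorin receptor (-1.39 at 8 h and -0.10 at 24 h, difference 1.30 ± 0.0985), CHD4 (0.90 ± 0.086) and SOX11 (0.96 ± 0.117). Those with a negative difference were AHNAK, a scaffold protein gene (1.15 at 8 h and -0.61 at 24 h, difference -1.76 ± 0.265), ATP2A3, a calcium pump of the endoplasmic reticulum (-1.36 ± 0.106), and IGLL1, a surrogate light chain gene (-1.28 ± 0.09). Of the 2358 genes past the test, 959 had a positive and 1399 a negative difference. With a replicate block within each time, 1359 genes passed. The share with a negative difference was 59.3% on the deposited scale, 48.4% after quantile normalisation, 41.1% on log2(CPM + 1) and 40.7% on log2(CPM + 5), so neither direction held across scalings. Without DMSO replicate 2 at 8 h, 1571 genes passed this test.

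**Figure D4:**
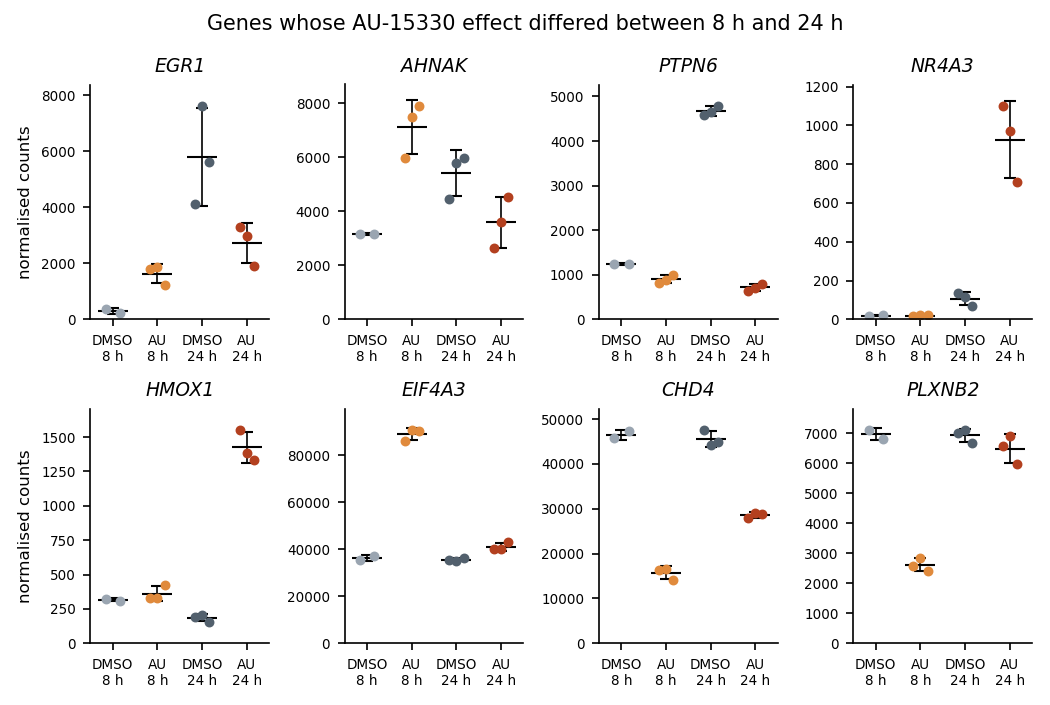
Normalised counts (vertical axes, linear from 0) of 8 genes whose response to AU-15330 differed between 8 h and 24 h, with 1 point per library and a bar for the mean ± SD of each group (DMSO at 8 h, n = 2; all other groups, n = 3). The EGR1 mean was 288 in DMSO and 1621 in AU-15330 at 8 h, and 5788 and 2722 at 24 h.

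By lists, B cell receptor signalling genes had a lower change at 24 h than at 8 h. The difference was positive for 1 of 31 members, negative for 15 and not past the test for 15 (1 and 18 adjusted over the list alone), with CD79A at -1.14 and BTK at -1.35. The camera adjusted p was 3.17e-08, and the adjusted p = 0.08 with an estimated correlation. MYC targets and ribosome biogenesis genes also had a lower change at 24 h, with 1 positive, 20 negative and 19 not past the test of 40 (1 and 25 adjusted over the list alone) and a median difference of -0.22. Within it NCL, the nucleolin gene, had a difference of -0.36 and POLR1B, a subunit of RNA polymerase I, of -0.80 (camera adjusted p = 3.17e-08, and adjusted p = 0.00864 with an estimated correlation). MHC class II genes had 0 positive, 8 negative and 6 not past the test (0 and 10 adjusted over the list alone), with CIITA at -0.82 and CD74 at -0.47 (camera adjusted p = 2.91e-05, and adjusted p = 0.08 with an estimated correlation). Much of the difference in B cell receptor signalling and MHC class II genes lay in DMSO, where time and batch cannot be told apart, since their mean differences were -0.46 and -0.449 and their mean shifts in DMSO from 8 h to 24 h were 0.279 and 0.23. Among p53 targets 12 of 25 members had a positive difference, 0 a negative one and 13 did not pass the test (14 and 0 adjusted over the list alone), with TP53INP1 at 1.87 and CDKN1A at 0.75 (camera adjusted p = 3.5e-06, and adjusted p = 0.097 with an estimated correlation). The 10 tested replication-dependent histone genes had 3 positive, 0 negative and 7 not past the test (6 and 0 adjusted over the list alone), with H2AC6 at 1.09 and H2BC21 at 0.85 (camera adjusted p = 0.0037, and adjusted p = 0.464 with an estimated correlation). The histone list has 51 members, so most of them were not tested. T cell markers went both ways, with differences of -0.69 in LCK, -1.16 in CD3G and 1.65 in CD28. Of the 4 tested, 1 had a positive difference, 2 a negative one and 1 did not pass the test.

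In DMSO alone, immediate early genes and NF-kappaB targets were higher at 24 h than at 8 h and heat shock genes were lower. Of 24 immediate early genes, 14 rose, 0 fell and 10 did not pass the test (20 and 0 adjusted over the list alone), with EGR1 at 4.06, EGR2 at 4.23, EGR3 at 3.53 and FOS at 3.26. The camera adjusted p was 2.13e-17, and the adjusted p = 0.0472 with an estimated correlation. Of 21 NF-kappaB targets, 14 rose, 0 fell and 7 did not pass the test (16 and 0 adjusted over the list alone), with the cytokine gene IL10 at 1.84 and TNFAIP3, a feedback inhibitor, at 0.98 (camera adjusted p = 9.06e-15, and adjusted p = 0.0199 with an estimated correlation). Of 15 heat shock genes, 0 rose, 12 fell and 3 did not pass the test (0 and 13 adjusted over the list alone), with DNAJB1 at -0.86 and HSPA8, a constitutive chaperone, at -0.59 (camera adjusted p = 3.79e-15, and adjusted p = 0.00928 with an estimated correlation). Unfolded protein response genes were also higher, with 10 of 18 up, 0 down and 8 not past the test (12 and 1 adjusted over the list alone), HSPA5 at 0.53 and XBP1 at 0.38 (camera adjusted p = 8.44e-07, and adjusted p = 0.0314 with an estimated correlation). The genes named in this comparison were chosen after their values were seen.

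B cell receptor signalling genes were higher in DMSO at 24 h too, with 14 of 31 up, 0 down and 17 not past the test (15 and 1 adjusted over the list alone), PTPN6 at 1.86 and MS4A1 at 0.54 (camera adjusted p = 2.56e-07, and adjusted p = 0.0502 with an estimated correlation). In DMSO 1287 of the 12721 genes passed the test between the times, 834 higher and 453 lower at 24 h. The share lower was 35.2% on the deposited scale, 47.4% after quantile normalisation, 49.8% on log2(CPM + 1) and 49.3% on log2(CPM + 5). Each time was its own batch in the labels, so time in culture and batch cannot be told apart in this comparison. The count was 688 without DMSO replicate 1 at 8 h, 661 without DMSO replicate 2 at 8 h and 851 without DMSO replicate 1 at 24 h.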

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

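Among the tests in this part, those of the scaling between libraries, of the DMSO shift, of a single DMSO library, of batch and of other splits of the libraries were chosen only after the result was seen. The genes and lists of the next paragraph were picked out by a test of the difference between the 24 h and 8 h effects of AU-15330, which 2358 genes passed, and the balance of falls and rises and the splits belong to the comparisons at each time.

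Among named genes, the log2 change at 24 h minus that at 8 h was -3.35 for EGR1, -2.17 for PTPN6, -1.83 for SH3TC1, -1.76 for AHNAK, -1.36 for ATP2A3, -1.31 for SASH3, -1.28 for IGLL1, -1.17 for CUX2, -1.09 for CD81 and -1.08 for EIF4A3. It was -0.852 for CD38, -0.68 for CD48, -0.565 for SOCS3, -0.542 for MYC, -0.479 for both ZMIZ1 and CXCR4, -0.449 for GADD45B, -0.412 for SPIB, -0.385 for SMARCA2, -0.384 for IGLC2 and -0.301 for SLC7A5. Positive differences were 0.273 for CD70, 0.506 for ADM, 0.776 for CCR7, 0.898 for CHD4, 0.912 for BTG2, 0.961 for SOX11, 1.23 for ZNF703, 1.3 for PLXNB2, 1.31 for CRYM, 1.46 for TYMP, 2.45 for HMOX1 and 2.56 for NR4A3. Of 134 other named list members, 69 passed the same test. Among lists, the median difference was -0.385 for B cell receptor signalling, -0.217 for MYC targets and ribosome biogenesis, 0.295 for p53 targets, -0.468 for MHC class II and 0.583 for replication-dependent histones.

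Large falls outnumbered large rises under AU-15330, with 481 against 122 genes at 8 h (a ratio of 3.94) and 609 against 209 at 24 h (2.91). After the median of bins of GC content and of transcript length was subtracted, the ratio was 4.1 at 8 h and 2.88 at 24 h. For the same genes it was 4.04 and 2.84 before that step. A shift common to genes of like GC content or length thus did not account for the ratio. A bias of GC content or length confined to large changes was not tested, since the step removes only bin medians. Among the 7827 genes averaging at least 1000 normalised counts the ratio was 3.48 and 4.27, which argues against depth as the whole cause. The common shift of all folds that would make falls equal rises was 0.28 at 8 h and 0.225 at 24 h. At 24 h this was 4.47 times the movement of the median of all genes from 0.00881 to 0.0591 on log2(CPM + 1). At 8 h the median moved from 0.0198 to 0.00952 on log2(CPM + 5). Quantile normalisation moved the 8 h median from 0.0094 to 0.0229 on the deposited scale, which is not directly comparable with that shift. That AU-15330 lowers the RNA of more genes by a large factor than it raises may therefore be kept as a biological hypothesis, found and tested on the same libraries. A change in the total RNA of the cells was not tested, since each library was scaled to the others.

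For 190 genes AU-15330 had opposite directions at the 2 times, 107 up at 8 h and down at 24 h and 83 the reverse. The median share of their difference that lay in the shift of DMSO between the times was 0.113 (95% interval 0.0795 to 0.157, from a bootstrap over genes), with 21 genes over 0.5. All genes share the same DMSO libraries, so the interval leaves out error between libraries. This median argues against the DMSO shift for most of the 190 but not for those 21. EGR1 was among the 21, and its DMSO mean rose from 288 to 5788 normalised counts. Of the 190 genes, 41 passed the test between the DMSO groups, against 1287 of the 12721 tested. Without 1 of the DMSO libraries at 8 h the count was 143 or 133, of which 113 and 107 were among the 190, so no single such library accounts for most of it, although only 59.5% and 56.3% of the genes remained. The times were separate batches, 1287 genes differed between the DMSO groups, and time and batch cannot be told apart in that shift. A course of response in which early and late effects differ in sign stays open and untested.

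The MYC target list was higher relative to DMSO at 8 h than at 24 h, with a median difference of -0.217 over 40 genes. Of 10000 random lists matched on abundance, 0 had a median difference at or below it, and their central 95% lay between -0.138 and -0.0145. The median of these random lists was -0.075, against -0.0225 for all genes, so genes of like abundance shared part of the difference. Under 3 other scalings the list stayed below the median of all genes, by -0.106 at the nearest. Centring library medians and rescaling to CPM shift the list and all genes about equally, so they could not test scaling. Quantile normalisation could, and its gap was -0.106, against -0.164 with library medians centred. These gaps are on the deposited scale, unlike the median difference of -0.217. The median share of the difference lying in the DMSO shift was -0.0433 (-0.217 to 0.0301, from a bootstrap over genes, which leaves out error between libraries). The tables thus argue against abundance as the whole cause and against the DMSO shift. Against scaling as the whole cause there is only quantile normalisation, after which the list still passed (camera adjusted p = 0.000197). A part played by scaling stays open. A higher level of MYC targets relative to DMSO at 8 h than at 24 h may be kept as a hypothesis. A batch acting differently on treated and control libraries was not tested. A fall at 24 h relative to other genes is not shown, as the list did not pass there (camera adjusted p = 0.0733, and 0.0756 to 0.328 over the scalings). Against no change, fry gave a fall at 24 h on the deposited scale (adjusted p = 5.32e-05). There 18 members were lower and 4 higher, against 15 lower and 9 higher after quantile normalisation.

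The libraries allow too few splits for a share under 0.05, with 10 splits at each time. At 8 h the labelled split gave 5624 genes and the highest other 0, and 1 of the splits gave as many. At 24 h it gave 6476 genes and the highest other 0, again with 1 split giving as many. For lists the labelled split gave 11 at 8 h and the highest other 15, with 3 splits giving as many, and 8 at 24 h and the highest other 7, with 1 split giving as many. Every other split mixes AU-15330 and DMSO libraries unevenly, so it still carries part of the treatment effect. The counts of the other splits, for genes and for lists, therefore do not show what chance alone gives.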

How the results depend on the processing

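The tests with voom, with entries of a symbol summed and on log2(count + 60) were chosen only after the data were seen. For 258 pairs of a named gene and a comparison, 23 alternatives gave 5916 values, of which 5810 kept direction and side of the threshold, 78 lost the call, 16 gained it and 12 turned direction, 0 of these among the 232 pairs past the threshold. The turned values belonged to genes that had not passed, and 1 of them passed after turning, CCND1 at 24 h after quantile normalisation. For PBRM1, 8 h, the value was -0.006163 on log2(CPM + 1), -0.006065 on log2(CPM + 5) and -0.03242 after quantile normalisation, and ranged from -0.03904 to 0.04228 when 1 library was left out. For CCND1, 24 h, it was 0.04027, 0.04021 and 0.1129 under the same settings and 0.001168 with library medians centred. For CD70, 8 h, it was -0.001977 with a replicate block and ranged from -0.001977 to 0.0467 when 1 library was left out. The cause was not tested. Requiring a difference of 1 on the deposited scale left 38 genes at 8 h, 90 at 24 h, 25 at both times, 10 for the difference between times and 8 in DMSO. On log2(normalised count + 60), where folds of low genes are still understated, 603, 818, 215 and 58 of the called genes changed by at least 1. These counts are for 8 h, 24 h, the difference and DMSO. Both the size asked for and the compression of the deposited scale thus lower the counts on the deposited scale. The lists past the threshold numbered 5 at 8 h and 0 at 24 h with the correlation estimated per list, and 18 and 17 with fry, which tests each list against no change and not against other genes. Apart from these and from the replicate block, which is given below, the other alternatives stayed within 1.5 times, at 5103 to 5694 genes at 8 h, 5712 to 6812 at 24 h, 2000 to 2357 for the difference, 1061 to 1339 in DMSO and 3509 to 4012 at both times. Leaving out 1 library gave 4397 to 5698 genes at 8 h, 5774 to 6480 at 24 h, 3169 to 3660 at both times, 11 to 13 lists at 8 h and 8 to 10 at 24 h. It gave 1571 to 2414 for the difference, the lowest without DMSO replicate 2 at 8 h, and 661 to 1355 in DMSO, with 688 without replicate 1 at 8 h, 661 without replicate 2 at 8 h and 851 without replicate 1 at 24 h. A group left with 1 library was assumed to vary like the other groups. With voom, 5605, 6417 and 2191 genes were shared with the calls at 8 h, at 24 h and for the difference. Of the smallest changes simulated 30% were recovered at 8 h and 44% at 24 h, with far fewer changed genes than in the data. The estimated counts per library, 50765418 to 67572111, and the group sizes were not varied. Their part in missed small changes was therefore not tested.

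Whether the replicate numbers pair the libraries is not settled. At 8 h the 2 DMSO libraries deviate from their mean as mirror images, so the check says little there. Deviations from group means of same-numbered libraries had correlations of -0.025 and -0.0349 at 8 h and 0.0411, 0.03 and 0.0446 at 24 h, where each library correlated best with its own number, a hint from the data only. With a replicate block within each time, which left 3 residual degrees of freedom in place of 7, the count was 1359 for the difference between times, 3336 at both times, 4763 at 8 h and 6185 at 24 h, and of the last pair 4558 and 5962 were among the genes called without the block. With a separate block shared by the DMSO libraries the count in DMSO was 798. Lists that passed camera only with the block within each time, or with it and some scalings, were histones at 24 h (adjusted p = 0.0188, and adjusted p = 0.615 with an estimated correlation), and for the difference between times heat shock (0.038, and adjusted p = 0.33 with an estimated correlation) and apoptosis (0.0282, and adjusted p = 0.269 with an estimated correlation). The estimated correlations came from the fit without the block.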

Other observations

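No test was added in this part after a result was seen, but some of the genes named were chosen after their values were seen. Apoptosis regulators went both ways under AU-15330, with 5 of 26 higher, 12 lower and 9 not past the test at 8 h (5 and 13 adjusted over the list alone, camera adjusted p = 0.18) and 9, 10 and 7 at 24 h (9 and 10 adjusted over the list alone, camera adjusted p = 0.883, with a median of 0.027 and a mean of -0.0159). BMF, a BH3-only sensitiser of apoptosis, changed by -1.77 ± 0.102 at 8 h and -0.29 at 24 h, a called difference of 1.48, and TNFRSF10B, a death receptor, by -0.95 ± 0.1 and -0.31. BBC3, which encodes PUMA, was at -0.44 and 0.52, FAS at -0.92 ± 0.138 at 24 h and BIRC3 at 0.68 ± 0.0839. NF-kappaB targets were 5 higher, 9 lower and 7 not past the test of 21 at 8 h (6 and 10 adjusted over the list alone, camera adjusted p = 0.207) and 6, 12 and 3 at 24 h (6 and 12 adjusted over the list alone, camera adjusted p = 0.131). IL10 changed by -2.33 ± 0.15 and -3.45 ± 0.134, whereas NFKB2 rose by 0.55 ± 0.0507 and 0.84 ± 0.0454 and RELB, its partner in the non-canonical pathway, by 0.95 ± 0.038 at 24 h. Immediate early genes were 9 higher, 4 lower and 11 not past the test of 24 at 8 h (9 and 4 adjusted over the list alone, camera adjusted p = 0.321) and 10, 11 and 3 at 24 h (11 and 11 adjusted over the list alone, camera adjusted p = 0.822). At 24 h NR4A2 rose by 1.91 ± 0.124 and DUSP4, a MAP kinase phosphatase, by 1.72 ± 0.13, while EGR3 was at -2.68. The difference between the times had a median of 0.0572 and a mean of -0.254 in this list.

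Hypoxia-inducible genes were 8 higher, 9 lower and 10 not past the test of 27 at 8 h (8 and 10 adjusted over the list alone, camera adjusted p = 0.95) and 9, 9 and 9 at 24 h (9 and 9 adjusted over the list alone, camera adjusted p = 0.761), and at 8 h the median was 0.0298 and the mean 0.0427 while camera's sign was negative, and positive on log2(CPM + 1). ADM rose at both times, ALDOC, an aldolase, rose by 1.92 at 24 h, and SLC2A1, a glucose transporter, changed by -0.91 ± 0.0796 at 24 h. Integrated stress response genes were 12 higher, 9 lower and 3 not past the test of 24 at 8 h (12 and 9 adjusted over the list alone, camera adjusted p = 0.579) and 10, 8 and 6 at 24 h (11 and 8 adjusted over the list alone, camera adjusted p = 0.663), with SLC3A2, the partner of SLC7A5, up by 0.53 ± 0.0395 and 0.73 ± 0.0353, and SHMT2, a mitochondrial serine enzyme, at -0.76 ± 0.0346 and -1.13 ± 0.0309. Heat shock genes were 6 higher, 4 lower and 5 not past the test of 15 at 8 h (6 and 4 adjusted over the list alone, camera adjusted p = 0.648) and 4, 7 and 4 at 24 h (4 and 7 adjusted over the list alone, camera adjusted p = 0.535), and the median at 24 h turned positive after quantile normalisation. Oxidative phosphorylation genes were 9 higher, 1 lower and 20 not past the test of 30 at 8 h (9 and 1 adjusted over the list alone, camera adjusted p = 0.092) and 11, 4 and 15 at 24 h (11 and 3 adjusted over the list alone, camera adjusted p = 0.342), with SDHA, a succinate dehydrogenase subunit, at -0.36 ± 0.0472 and -0.62 ± 0.0422. Of 33 cytosolic ribosomal protein genes, 1 rose and 32 did not pass the test at 8 h (1 and 0 adjusted over the list alone, camera adjusted p = 0.939, median -0.011, which was positive after quantile normalisation, and mean 0.0242), and 4 rose, 3 fell and 26 did not pass at 24 h (1 and 1 adjusted over the list alone, camera adjusted p = 0.822). The counts at 24 h turned with the scaling, with 11 higher and 0 lower on log2(CPM + 1) and 7 and 2 after quantile normalisation. Of 12 mitochondrially encoded genes, 0 passed the test at 8 h (0 and 0 adjusted over the list alone, camera adjusted p = 0.158) and MT-ND3 passed at 24 h (0 and 0 adjusted over the list alone, camera adjusted p = 0.822). Of the 10 replication-dependent histone genes tested from a list of 51, 1 fell and 9 did not pass at 8 h (0 and 0 adjusted over the list alone, camera adjusted p = 0.362), and 4 rose, 1 fell and 5 did not pass at 24 h (5 and 1 adjusted over the list alone, camera adjusted p = 0.0835), with H3C8 at 0.62 ± 0.124.

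Markers of other cell types moved in different directions. Of 5 fibroblast and epithelial markers, 3 fell and 2 did not pass the test at 8 h (0 and 3 adjusted over the list alone, camera adjusted p = 0.118) and 4 fell and 1 did not pass at 24 h (0 and 4 adjusted over the list alone, camera adjusted p = 0.131), with COL1A1, a collagen gene, at -1.59 ± 0.293 and -2.83 ± 0.262. Of 3 myeloid markers, CST3 fell by 0.78 at 8 h (0 and 1 adjusted over the list alone), and at 24 h CD68 rose by 1.04 ± 0.108 while CST3 (-0.54 ± 0.0824) and AIF1 (-0.49 ± 0.162) were lower (1 and 2 adjusted over the list alone), with a median of -0.492 and a mean of 0.00454. EPOR, the only tested erythroid and megakaryocyte marker, rose by 0.44 ± 0.11 and 0.88 ± 0.0981 (1 and 0 adjusted over the list alone). Z138 is a cell line, and no sort or gate is described in the labels.

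In DMSO alone further lists differed between 24 h and 8 h, most of them higher at 24 h, where time and batch cannot be told apart. S phase and DNA replication genes were 10 higher, 0 lower and 25 not past the test of 35 (13 and 1 adjusted over the list alone), with CDC6, a replication licensing factor, at 0.24 ± 0.04 and TK1, a thymidine kinase, at 0.20 ± 0.0374 (camera adjusted p = 0.00042, and adjusted p = 0.0245 with an estimated correlation). Integrated stress response genes were 4 higher, 1 lower and 19 not past the test of 24 (7 and 1 adjusted over the list alone), with PPP1R15A, which encodes GADD34, at 0.72 ± 0.0901 (camera adjusted p = 0.0046, and adjusted p = 0.0491 with an estimated correlation). B cell transcription factors were 9 higher, 1 lower and 18 not past the test of 28 (10 and 1 adjusted over the list alone), with PAX5 at 1.00 ± 0.111 and BACH2, a repressor of plasma cell fate, at 0.85 ± 0.11 (camera adjusted p = 6.22e-05, and adjusted p = 0.0604 with an estimated correlation). MHC class II genes were 4 higher, 0 lower and 10 not past the test of 14 (6 and 0 adjusted over the list alone), with CIITA at 0.49 ± 0.095 (camera adjusted p = 0.000906, and adjusted p = 0.0604 with an estimated correlation). Mitosis genes were lower, with 0 of 35 up, 5 down and 30 not past the test (1 and 6 adjusted over the list alone), CDC20, an activator of the anaphase-promoting complex, at -0.29 ± 0.0438 (camera adjusted p = 0.0399, and adjusted p = 0.335 with an estimated correlation). Lists that were also higher by camera and lost the call with an estimated correlation were hypoxia (4 up and 0 down, 4 and 0 adjusted over the list alone, camera adjusted p = 0.0046, adjusted p = 0.256 with an estimated correlation), with SLC2A3 at 1.42 ± 0.146, and homing (5 and 0, 7 and 2 adjusted over the list alone, camera adjusted p = 0.0046, adjusted p = 0.107 with an estimated correlation), with ITGA4 at 0.55 ± 0.0697. The same held for p53 targets (5 and 1, 6 and 1 adjusted over the list alone, camera adjusted p = 0.00942, adjusted p = 0.22 with an estimated correlation), with FDXR at 0.51 ± 0.0733, and interferon genes (5 and 0, 6 and 0 adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.0604 with an estimated correlation). It held too for plasma cell genes (6 and 0, 6 and 3 adjusted over the list alone, camera adjusted p = 0.0409, adjusted p = 0.164 with an estimated correlation), ribosomal proteins (2 and 0, 1 and 0 adjusted over the list alone, camera adjusted p = 0.0046, adjusted p = 0.416 with an estimated correlation) and mitochondrially encoded genes (0 and 0, 0 and 0 adjusted over the list alone, camera adjusted p = 0.00261, adjusted p = 0.416 with an estimated correlation).

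For the 24 h effect minus the 8 h effect, mitosis genes passed camera after quantile normalisation (adjusted p = 0.000733, against 0.000733 to 0.337 over 3 scalings, and adjusted p = 0.808 with an estimated correlation on the deposited scale), with 3 of 35 positive, 1 negative and 31 not past the test before it (2 and 1 adjusted over the list alone, camera adjusted p = 0.353). Apoptosis regulators, with BMF at 1.48 and BBC3 at 0.95, missed the threshold with a camera adjusted p of 0.0526 and passed after quantile normalisation (0.0382) and on log2(CPM + 1) (0.0479) but not with library medians centred (0.0604) or with an estimated correlation (adjusted p = 0.269).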
